A study of Mus musculus with 36 samples.

How the data were processed

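The assay was ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, on mouse trophoblast stem cells carrying the In(X)1H inversion, per the labels. The cells were kept in medium conditioned by mouse embryonic fibroblasts, transfected for 4 hours with shRNA vectors that also express mCherry, cultured for a further 44 hours, and sorted by fluorescence, per the labels' protocols. Libraries were amplified with Nextera primers, per the labels' protocols. The 36 samples form 4 groups of 9 libraries, from 3 biological replicates with 3 libraries each. Groups and replicates were read from the sample titles.

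The submitters' processing notes name cutadapt 1.9.1, BWA 0.6.2, Picard, SAMtools 1.3.1, bedtools 2.26.0, MACS2 2.1.1.20160309 and HOMER 4.8, with the build mm10; they give no order or settings in the sources used here. Whether reads were shifted for the transposase, how duplicates were handled and which background the caller used are not given in the sources used here. Each group has 1 broad peak list, and the labels of all 9 of its libraries name that same list, so it was taken as a pooled list with no value per replicate. Per the labels and the layout of a broad peak file, each deposited peak carries a fold (a ratio of signal over background) that is the authors' own value. The deposited lists also give the −log10 p and the −log10 q of each peak, as the authors' caller wrote them. These values were used to describe, rank or filter peaks within a list. The lowest −log10 q in a list was between 1.00 and 1.01, so the lists reach down to a q of 0.1. The number of reads behind each list is unknown, and so is the precision it gives; intervals on shares of regions are exact binomial (Clopper-Pearson) intervals at 95% and cover counting error only.

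Peaks of the 4 lists that overlapped by at least 1 bp were merged into union regions. A region is called knockdown-only when it holds a peak of the knockdown list and of no other list, and knockdown-absent when the 3 control lists hold it and the knockdown list does not. With 1 list per group there is no replicate error, so the same 2 counts were made with each control list as the odd one, and these give the list-to-list background. This background is not neutral. A region that a control list alone lacks must be held by the knockdown list, so a knockdown list that differs from the rest lowers these control counts. With 4 lists, the smallest share that such a rotation can give is 0.25, so no p-value is given.

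Regions were assigned to the nearest of 21887 protein-coding genes of the GRCm38.p6 gene table within 50 kb. That assembly has the same primary coordinates as mm10. The table has no strand and no transcripts, so the distance was measured to the gene span in place of the transcription start that the design had set, and "at a gene end" means within 1 kb of either end of a span. Of the union regions, 74.9% were assigned to a gene, and 48.7% touched a gene span.

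18 gene lists were fixed before the data were examined: trophoblast stem cell, trophoblast giant cell, spongiotrophoblast and ectoplacental cone, syncytiotrophoblast, embryonic pluripotency, extraembryonic endoderm, fibroblast, Hox, cell cycle and endoreduplication, interferon and foreign nucleic acid, stress and p53, adhesion and cytoskeleton, FGF and ERK, activin and TGF-beta, Hippo, AP-2 and GATA factors, AP-1 factors, and housekeeping genes. All members were found in the gene table except that 20 of 22 interferon genes were. A list's share of knockdown-only or knockdown-absent regions was placed as a percentile among 10000 random gene lists of the same size, matched gene by gene on 20 bins of the number of regions per gene. These percentiles describe the deposited lists.

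The rule for named genes was also fixed before the data were examined. It takes Cdx2 and Tfap2c with each region within 50 kb, the 10 genes with the strongest knockdown-only region by −log10 q in the knockdown list and the 10 with the strongest knockdown-absent region by −log10 q in the scrambled mCherry-positive list. It also takes the 5 genes with the highest and the 5 with the lowest difference between both counts, and up to 4 genes per direction from each gene list. Genes named outside this rule are said to be chosen after their values were seen.

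Alternatives fixed at the same time were overlaps of 25% and 50% of the shorter peak, −log10 q of at least 3 and 5, lists of equal length, merging across gaps of up to 500 bp, peaks of at least 300 bp, autosomes only, leaving out 1 control list at a time, gene distances of 10 and 100 kb, gene ends of 2.5 kb and windows of 5 Mb instead of 1 Mb. The design also held a search for 26 motifs, which needs a genome sequence, so motifs were not analysed here. The steps were tested on simulated data: all 8 planted class counts over 20000 simulated regions were recovered, and of 200 simulated gene lists of 20 genes with a share 3 times the background, 97% lay above the central range that should hold 95% of unchanged lists, while 1.5% of 200 unchanged lists lay outside it. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.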

Results

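Open chromatin was mapped by ATAC-seq in mouse trophoblast stem cells, the self-renewing cells that give rise to the placental trophoblast, 48 hours after transfection with an shRNA against Cdx2. CDX2 is a homeobox transcription factor required to maintain these cells. 4 groups were compared: knockdown cells sorted as mCherry-positive, cells given a scrambled shRNA and sorted as mCherry-positive, mCherry-negative cells from the scrambled transfection, and untransfected cells. Each group had 9 libraries, 3 from each of 3 biological replicates, and was represented by 1 pooled peak list. The knockdown list held 139637 peaks over 82.3 Mb, and the control lists held 141463 to 145718 peaks over 80.3 to 86.1 Mb. Median peak width was 443 bp in the knockdown and 409 to 443 bp in the controls. Peaks with a −log10 q of at least 20 numbered 21598 in the knockdown list, against 23929 to 26631 in the control lists. Sequencing depth is unknown, and no value below has a replicate error.

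At the targeted gene, the knockdown list kept the accessible regions that touch Cdx2. Cdx2 lies on chromosome 5 at 147300900 to 147307249 (mm10), and all 3 regions touching this span were held by all 4 lists. Of 19 regions within 50 kb of the gene, 12 were held by all 4 lists, none was knockdown-only and 2 were knockdown-absent. Both knockdown-absent regions lay beyond the gene's higher-coordinate end. The first, at 147317961 to 147318264, was nearest to Urad and had a −log10 q of 1.52 to 3.91 in the controls. The other, at 147331677 to 147331800, was nearest to Flt3, a receptor tyrosine kinase gene, and reached 1.88 to 3.49. A 299 bp region at 147297849 to 147298147, 2753 bp from Cdx2, was held by the knockdown, scrambled mCherry-negative and untransfected lists and not by the scrambled mCherry-positive list. Some regions of all 4 lists were weaker by −log10 q in the knockdown than in every control. They included 147276842 to 147278829 (43.5 against 60.8 to 73.2) and, touching Cdx2, 147299112 to 147301443 (19.5 against 22.2 to 31.6). Only 147314981 to 147315937 was stronger than in every control (17.2 against 14.2 to 15.5), and others lay within the control range. Depth is unknown, so whether these differences belong to this locus is open. An shRNA acts on the transcript, so accessibility at the gene is no check of the knockdown.

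**Figure D1:**
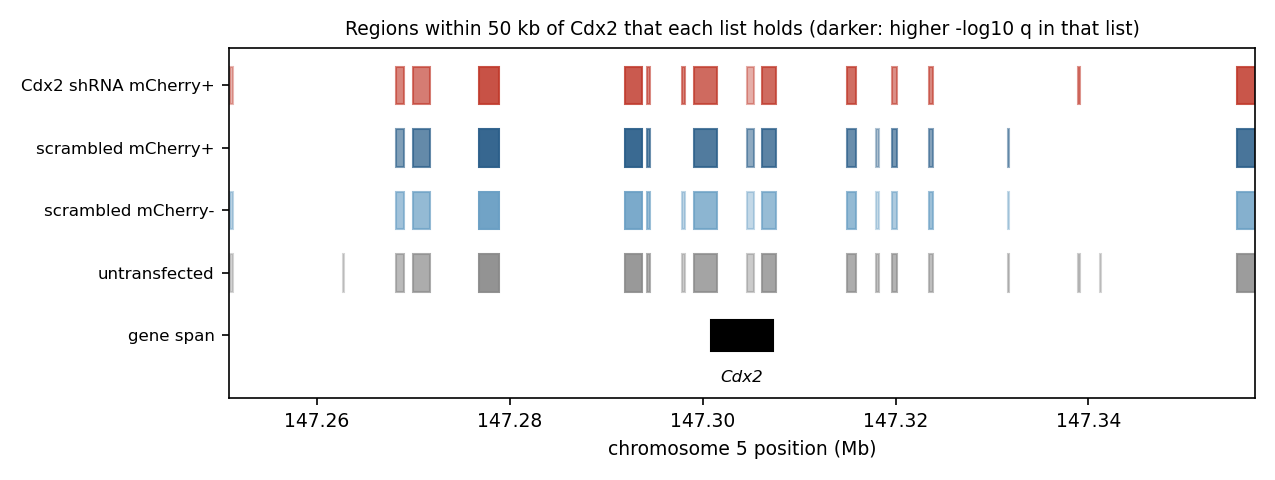
Regions held by each of the 4 peak lists (rows) along chromosome 5, in Mb, within 50 kb of Cdx2; the black box is the gene span, and a darker block has a higher −log10 q in its own list. The 3 regions touching Cdx2 appear in all 4 rows, and the 2 regions missing from the knockdown row alone lie to the right of the gene.

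Tfap2c encodes the transcription factor AP-2 gamma, which trophoblast stem cells also require and which the study's title names. It lies on chromosome 2 at 172545678 to 172558622, with 30 regions within 50 kb, 18 of them held by all 4 lists. The region at 172513708 to 172514094, 31584 bp from the gene, was knockdown-absent, with a −log10 q of 3.99 in the scrambled mCherry-positive list, 4.45 in the mCherry-negative list and 2.59 in the untransfected list. The region at 172561313 to 172561549, 2691 bp from the gene, was knockdown-only, with a −log10 q of 1.64. Some regions of all 4 lists were weaker in the knockdown list. At 172576751 to 172577683 the −log10 q was 16.1, against 37.8 to 41.5 in the controls, with a fold of 3.29 against 4.17 to 4.26. At 172544093 to 172545273, 405 bp from the gene, it was 15.9 against 28.2 to 33.2. Others lay within the control range, such as 172569743 to 172571372 (19.1 against 18.6 to 26.0). Depth is unknown, so whether these differences belong to this locus is open.

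Relative to the control counts, the knockdown list stood apart more by the regions it alone lacked than by those it alone held. The lacked regions included a region inside Snrnp40 and a region near Btc. The 4 lists merged into 210120 regions, of which 94562 were held by all 4. The knockdown list alone lacked 8481 regions, against 3343 for the scrambled mCherry-positive list, 4122 for the scrambled mCherry-negative list and 5196 for the untransfected list. It alone held 18820 regions, against 16322 to 17699 for the controls, a count 1.06 times the highest control. Most regions of a single list were weak: 80.1% of the knockdown-only regions had a −log10 q under 2, and their median −log10 q was 1.46, against 7.06 in the same list for regions of all 4 lists.

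With regions counted as held only at a −log10 q of at least 5, and as lacking only where the deposited list had no peak, the knockdown list lacked 280 regions and the controls 4 to 18. On this count the knockdown list alone held 252 regions, the scrambled lists 75 and 72 and the untransfected list 167. The knockdown list thus differed in both directions, with about as many regions held alone as lacked. In an alternative chosen after the data were seen, which also left out peaks with such a −log10 q but a fold under 1.5, these counts became 236 for the knockdown and 43 to 71 for the controls. With a −log10 q of at least 5 in every list, the knockdown-only count of 3695 was no longer the highest, as the scrambled mCherry-positive list alone held 3774. The rotation has 4 positions, so the knockdown's place as the extreme list for absent regions cannot reach a share below 0.25 by itself.

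**Figure D2:**
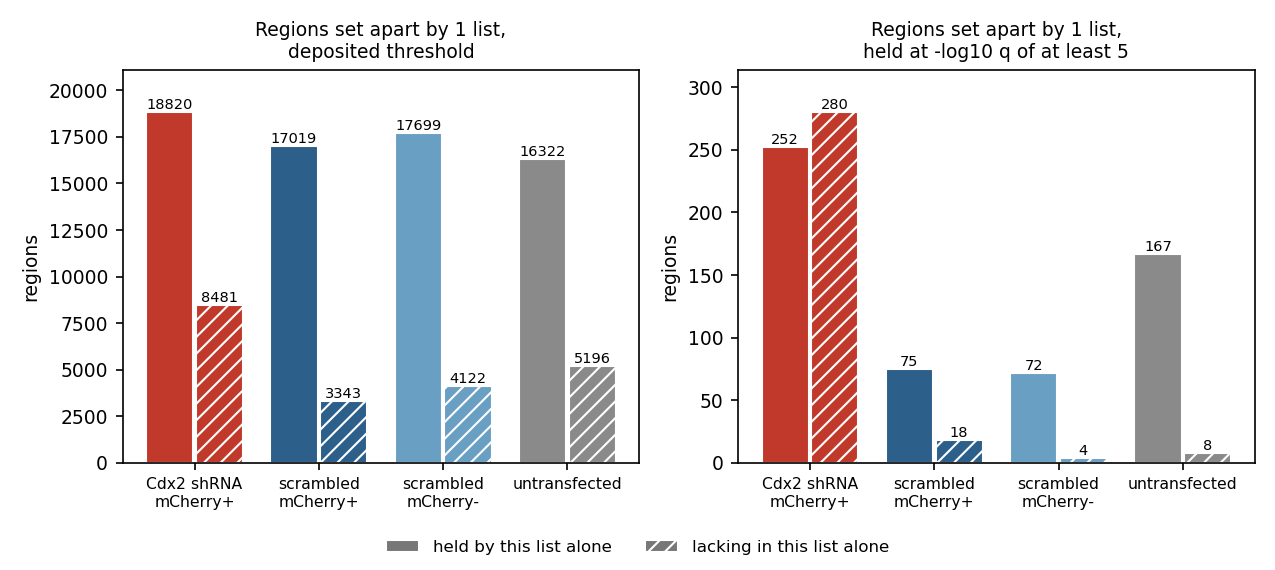
Number of union regions that each of the 4 lists holds alone (plain bars) or alone lacks (hatched bars), at the deposited threshold (left) and with presence counted at a −log10 q of at least 5 (right). The knockdown list alone lacks 8481 regions on the left and 280 on the right, more than any control list in both.

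Knockdown-absent regions were ranked by their −log10 q in the scrambled mCherry-positive list. An 86 bp region inside Hexb, which encodes a lysosomal hexosaminidase subunit, lay on chromosome 13 at 97190547 to 97190632 with a −log10 q of 48.8 to 57.6 in the controls; the shortest peak of the knockdown list was 87 bp, so its absence there can come from the list's minimum width. A 937 bp region inside Snrnp40, a gene of the U5 spliceosomal particle, lay on chromosome 4 at 130371308 to 130372244 with 43.7 to 58.8. A region 13708 bp from Btc, which encodes the EGF-family ligand betacellulin, lay on chromosome 5 at 91416702 to 91417052 with 12.5 to 16.8. Regions inside Knl1, a kinetochore scaffold gene, Cep70, a centrosomal protein gene, and Slain2, a microtubule-binding protein gene, had 16.3, 16.8 and 18.2 in the scrambled mCherry-positive list. The region near Hs3st3b1 ranked first, at 92.9, but had 1.94 and 2.44 in the other controls, and that in Tram2 had 33.0 against at most 5.86. With Tex35 (19.3) these completed the named genes of this set, with folds of 1.16, 1.19 and 1.26 in the ranking list, and the remaining region lay near an uncharacterised gene on chromosome 12. The authors' fold exceeded 5 in all 3 control lists at Hexb and Snrnp40.

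The strongest knockdown-only regions lay near Nfat5, Jup, Tm4sf1, Aig1, Lpp, Wap, Xpo1, Ero1a, Fam184b and Eif1. Those at Nfat5, the transcription factor of the osmotic stress response, Jup, which encodes the junction protein plakoglobin, and Tm4sf1 combined a −log10 q of 89.8, 66.3 and 45.5 with folds of only 1.40, 1.13 and 1.48. Wider regions with a higher fold lay 25348 bp from Aig1 (chromosome 10 at 13894386 to 13895504, −log10 q 27.8, fold 4.25), inside Lpp, a focal adhesion gene (chromosome 16 at 24802937 to 24803922, 25.6, fold 4.17), and 7131 bp from Fam184b (chromosome 5 at 45646632 to 45647330, 20.1, fold 3.74). Regions at Wap, Xpo1, Ero1a and Eif1 were 105 to 166 bp wide with folds of 1.26 to 1.53.

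Counted per gene, the highest excess of knockdown-only over knockdown-absent regions fell in Dpp10 (92 against 11), Thsd7b (54 against 12), Cntnap5b (35 against 1) and Cntnap5a (25 against 0) on chromosome 1, and in Sgcd (38 against 7) on chromosome 11. The scrambled mCherry-positive list alone held 94 regions in Dpp10 and 39 in Sgcd, so these genes gathered regions of a single list in a control as well. The opposite difference was small and fell in Camta1 (1 against 7), Dab1 (0 against 6), Grip1 (1 against 7), Lsamp (1 against 6) and Npas3 (0 against 5). In these 5 genes no control list alone lacked more than 2 regions. They were chosen for their knockdown counts, so lower control counts can follow from the choice. Genes were not chosen in the same way for the control lists.

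Genes of the stem cell state and of its differentiated fates carried knockdown-absent regions at about the rate of random gene lists. The 20 trophoblast stem cell genes had 394 regions, of which 15 in 10 genes were knockdown-absent (3.81%, percentile 44.1 among random lists) and 18 were knockdown-only (4.57%, percentile 0.34). Control lists gave percentiles of 0.44 to 26.2 for the latter. Knockdown-absent regions with the highest −log10 q in this list lay near Ets2 (4.84 in the scrambled mCherry-positive list), Tfap2c, Sall4 (3.69) and in Esrrb (3.13), and knockdown-only regions lay in Ddah1 (3.90) and Fgfr2, the FGF4 receptor gene (3.73), and near Dusp6 (2.62) and Zic3 (1.95). The 17 trophoblast giant cell genes had 146 regions, 6 knockdown-absent (percentile 53.6) and 4 knockdown-only (percentile 0.70, controls 25.3 to 37.5). A region 4692 bp from Hand1, a transcription factor gene of giant cell differentiation, was knockdown-absent with a −log10 q of 7.03 to 8.91 in the controls, while another, 23450 bp from Hand1, was knockdown-only at 2.51. Knockdown-absent regions also lay near Prl2c2, the proliferin gene (7.70 in the scrambled mCherry-positive list), and Flt1 (4.19), and the other knockdown-only regions near Gata2 (2.08), Mmp9 (1.34) and Gata3 (1.26).

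Among other trophoblast fates, syncytiotrophoblast genes had 7 knockdown-absent regions of 132 (percentile 80.6), including regions near Gjb2 (4.66) and in Gcm1 (2.81), the transcription factor gene of syncytiotrophoblast, and 8 knockdown-only regions (percentile 19.3), of which the strongest lay in Fzd5 (8.13). Spongiotrophoblast and ectoplacental cone genes had 4 of 108 knockdown-absent (3.70%), as many as the highest control count, and 9 knockdown-only (percentile 54.5), with examples of the former in Egfr and Igf2. Hox genes had 5 of 66 knockdown-absent (7.58%, percentile 90.1), in Hoxc4 (6.85), Hoxd3 (4.56), Hoxc6 (3.81) and Hoxb3 (2.32), against 0 to 2 in control lists. Pluripotency genes had 2 of 86 (percentile 23.3), in Prdm14 and near Zfp42, and extraembryonic endoderm genes had 3 of 126 (percentile 14.8), near Sparc, Pdgfra and Gata6. Fibroblast genes, fixed because the medium was conditioned by fibroblasts, had 8 of 144 (percentile 79.7), with examples near Twist2 (5.16) and in Col1a1 (2.99).

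The remaining lists cover signalling, adhesion, cell cycle, stress and housekeeping genes. Knockdown-absent regions numbered 9 of 233 for FGF and ERK genes (percentile 46.8), with the strongest 3900 bp from Spry2 (7.13), 8 of 271 for Hippo genes (20.5), with the strongest near Amotl2 (6.38), and 2 of 127 for activin and TGF-beta genes (5.41), in Smad7 and near Inhba. AP-2 and GATA genes had 7 of 129 (percentile 80.6), with the strongest 72 bp from Tfap2a (8.46), and AP-1 genes 1 of 68 (14.6), near Fos. Adhesion and cytoskeleton genes had 10 of 319 (percentile 21.4), near Cdh2 (7.43) and Krt18 (5.72) and in Myh9 (6.65) and Itgav (6.12). Cell cycle and endoreduplication genes had 6 of 178 (percentile 31.9), with the strongest near Cdk1 (7.36), stress and p53 genes 1 of 94 (5.43) and housekeeping genes 3 of 50 (71.4). The interferon and foreign nucleic acid genes had 0 of 80 (percentile 1.95), against 1 to 4 in control lists (percentiles 41.5 to 98.3). It was the only 1 of the 18 lists outside the central 95% for knockdown-absent regions, about as many as chance gives. For knockdown-only regions 4 of the 18 lists lay below the central 95% and 0 above, against 1 or 2 below and 0 above in each control rotation. The random lists were matched on the number of regions per gene, not on their strength or chromosome, and most single-list regions were weak. Low percentiles for knockdown-only regions, also in the stem cell and giant cell lists, can therefore come from the matching. Knockdown-only regions numbered 0 of 68 for AP-1 genes (percentile 0.46, controls 4.24 to 10.0) and 2 of 94 for stress and p53 genes (2.08, controls 17.5 to 74.6), and the highest percentile among the 18 lists was 79.4, for activin and TGF-beta genes, with regions near Skil (3.01) and in Smad3 (2.88).

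Against the matched control, the scrambled mCherry-positive cells, the knockdown list shared fewer regions than any 2 control lists shared with each other. The pair merged into 173600 regions, of which 108329 (62.4%) were shared, 29920 were held by the knockdown list alone and 35351 by the scrambled list alone. By covered bases the overlap was 63.4% of the union. The knockdown shared 60.8% of regions with the scrambled mCherry-negative list and with the untransfected list alike. At a −log10 q of at least 5 in every list, it shared 75.5% with the scrambled mCherry-positive list, against 81.8% to 83.3% between control lists. At the deposited threshold, the scrambled mCherry-positive list held 35351 regions that the knockdown list lacked. It held 30811 that the mCherry-negative list lacked and 32827 that the untransfected list lacked, a smaller gap than in the rotation.

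The control lists were closer to each other. Transfection and sorting are seen only against the untransfected cells, since the mCherry-negative cells came from the same scrambled transfection and were sorted too. The scrambled mCherry-positive list shared 65.0% of regions with the mCherry-negative list and 64.5% with the untransfected list. By covered bases these overlaps were 66.7% and 66.0%, and the mCherry-negative and untransfected lists shared 64.1% of regions and 66.7% of bases. With 1 list per group, how far such shares vary between replicates is unknown.

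Regions of a single list lay away from gene ends. Of the regions held by all 4 lists, 16.2% lay at a gene end (95% exact interval 15.9 to 16.4%), against 3.01% (2.77 to 3.27%) of knockdown-only and 5.67% (5.19 to 6.19%) of knockdown-absent regions. Control lists gave 3.55 to 4.44% for regions they alone held and 4.14 to 4.94% for regions they alone lacked, and the interval of the highest, the scrambled mCherry-positive list (4.23 to 5.73%), overlapped that of the knockdown. With presence counted at a −log10 q of at least 5, the knockdown-absent share was 2.14% (0.790 to 4.61%) of 280 regions.

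By chromosome, 25.8% of knockdown-only regions lay on chromosome 1, which held 12.6% of the regions of all 4 lists, and the control lists put 24.8 to 26.8% of their own single-list regions there. Knockdown-absent regions were on chromosome 1 in 16.9% of cases, against 25.6 to 26.1% for the regions that each control list alone lacked. Chromosome 11 held 10.3% of knockdown-only regions and 10.3 to 13.8% in the controls. The most loaded 1% of 1 Mb windows held 6.68% of knockdown-only and 5.15% of knockdown-absent regions, and 7.14 to 7.40% and 8.03 to 11.4% in the control rotations. A list with fewer such regions fills fewer windows, and these shares were not corrected for that.

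**Figure D3:**
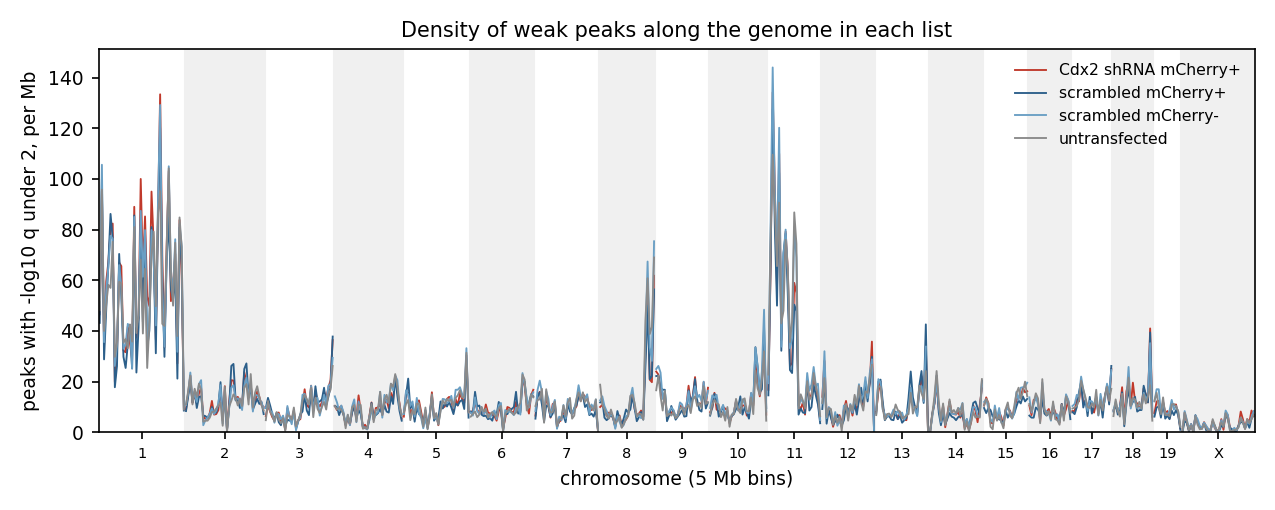
Peaks with a −log10 q under 2 per Mb, in 5 Mb bins along chromosomes 1 to 19 and X, with 1 line per peak list. Over the 4 lists, the average was at least 55.8 per Mb on chromosome 1, 58.8 on the first 70 Mb of chromosome 11 and 38.8 on chromosome 8 from 110 Mb.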

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

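The tests of the knockdown pattern, the peak width, the density of strong peaks, the background per segment and its floor were chosen after the results were seen; the distance between peaks and the fold and overall background readings of extra copies were chosen before. Both readings of extra copies gave the outcome that had been written in advance as counting against them. The reasons given below for leaving both undecided were added after the values were seen.

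The knockdown list alone lacked 8481 regions, 1.63 times the highest control count, and more than any control list in each of the 12 alternatives fixed in advance. A shorter knockdown list is argued against, since with lists of equal length the knockdown still lacked 7844 regions, 1.63 times the highest control. Transfection and sorting for mCherry cannot be decided from these counts. The knockdown lacked at least 1.89 times as many regions as the scrambled mCherry-positive list in all 17 settings that hold both. But a region that either of these lists alone lacks is held by the other, so a loss common to both enters neither count. At the deposited threshold such a loss would fall among the 4201 regions held by the scrambled mCherry-negative and untransfected lists only. In 4 settings on stronger regions the scrambled mCherry-positive list lacked more than the other controls. For the strongest 50000 peaks against the strongest 100000 it lacked 9, the other controls 1 and 1, and the knockdown 156. A knockdown list of fewer reads or lower signal cannot be told apart from a knockdown effect: the SD of its rank shift was 1.46 times that of the highest control, in both directions, the depth is unknown, and noisier ranks could also produce step losses. Its median −log10 q over regions of all 4 lists was the lowest (7.06 against 7.48 to 8.67). It also had the fewest peaks with a −log10 q of at least 5 (59297 against 61372 to 65906). Its median fold lay within the control range (2.00 against 1.92 to 2.01). The background that fold and −log10 p imply on autosomes outside the dense segments below was lowest in the knockdown list (22.6 against 23.8 to 26.4). How this background relates to depth was not tested. A batch of libraries or cells that holds the knockdown alone cannot be told apart either, because the number of knockdown lists is 1, and loss of CDX2 stays open and was not tested.

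A small set of peaks combined a −log10 q of at least 20 with a fold under 1.5 in 1 list alone: 3 in the knockdown, 11 in each scrambled list and 80 in the untransfected list. In the untransfected list, 39 single-list peaks carried the same deposited pair of values, a fold of 1.26 and a −log10 q of 103. Tandem copies that the assembly lays out in full would place such peaks beside each other, but 3.81% lay within 10 kb of another. Tandem copies that the assembly holds as 1 would pile up reads at an isolated place, so this spacing cannot decide on them. Open chromatin of 1 group would give peaks as wide as other strong ones, and their median width was 13.7% of that of strong peaks shared with another list. How the caller wrote these values, tandem copies held as 1 and scattered repeats stay open and were not tested. The regions at Nfat5, Jup and Tm4sf1 belong to this set.

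Peaks with a −log10 q under 2 were 5.43 to 5.93 times as dense on chromosome 1 as on the median of the other autosomes in the 4 lists, 5.83 to 6.35 times on the first 70 Mb of chromosome 11, 3.85 to 5.19 times on chromosome 8 from 110 Mb and 2.12 to 2.78 times on chromosome 10 from 105 Mb. More regulatory elements would raise peaks with a −log10 q of at least 20 as well, yet across the border on chromosome 11 weak peaks differed at least 4.29 times within a list and strong peaks 0.883 to 1.04 times. On chromosomes 1, 8 and 10 the ratio for strong peaks was at most 0.591 of that for weak peaks, which argues against such elements as the whole cause there, while a part stays open, as strong peaks were also denser (1.71 to 1.82 times on chromosome 8 from 110 Mb). Extra copies of these segments may underlie the density and cannot be told apart from other sources: the fold of regions at gene ends was at most 0.933 times that of other autosomes, but copies that raise signal and background alike cancel in a fold. The median background implied below was raised in the parts of chromosomes 8 and 11. It was not raised on chromosome 1 or on the part of chromosome 10, where this reason has less hold. The background that fold and −log10 p imply was at most 1.04 times that of other autosomes (1.15 to 1.19 on chromosome 8 from 110 Mb, 1.05 to 1.11 on the first 70 Mb of chromosome 11, 1 on chromosome 1 and on chromosome 10 from 105 Mb), but on other autosomes 58.1 to 62.2% of peaks sat at the commonest value of their list and at most 4.63% below it, against 22.5 to 30.9% and 32.9 to 42.6% at that value in the parts of chromosomes 8 and 11, so the background compared against lies at a floor and these ratios can understate a gain.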

How the results depend on the processing

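Alternatives that use a −log10 q of at least 3 for presence, leave out chromosomes or peaks of low fold, or rank the strongest peaks were chosen after the data were seen. Counts moved strongly with the threshold, while the knockdown's place as the list with the most absent regions held in all 12 alternatives fixed in advance, at 1.27 to 15.6 times the highest control; the knockdown-only count was the highest in 11 of the 12. Knockdown-only regions fell from 18820 to 5518 and 3695 with a −log10 q of at least 3 and 5 in every list, to 252 with at least 5 for presence only, and to 10055 with peaks of at least 300 bp. Knockdown-absent regions went from 8481 to 4937, 280 and 5041 under the last 3 of these, and to 12771 and 13349 when the scrambled mCherry-positive or the untransfected list was left out, since 2 lists then define the class. In those chosen after the data were seen, knockdown-only and knockdown-absent counts were 1206 and 1222 with a −log10 q of at least 3 for presence, 10470 and 5421 without chromosomes 1, 8, 10 and 11, 236 and 279 with at least 5 for presence and without peaks of low fold, 262 and 156 for the strongest 50000 peaks against the strongest 100000, and 93 and 54 for 20000 against 40000. For 20000 against 40000 the untransfected list alone held 111, more than the knockdown. Fewer peaks enter under the stricter settings by construction.

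The knockdown and scrambled mCherry-positive lists shared 60.0%, 75.5% and 63.1% of regions with 50% overlap, with a −log10 q of at least 5 and with equal length. The scrambled mCherry-positive list shared 62.3%, 82.6% and 66.7% with the mCherry-negative list and 62.0%, 81.8% and 65.6% with the untransfected list. At gene ends, knockdown-only and knockdown-absent shares were 6.77% and 11.4% within 2.5 kb, and 4.76% and 2.14% with a −log10 q of at least 5 for presence. In the latter the order turned, with overlapping intervals (2.48 to 8.17% and 0.790 to 4.61%), and the cause was not tested. In 5 Mb windows the most loaded 1% held 5.39% and 3.83%. Of 72 alternative values for the knockdown-absent shares of gene lists, 52 stayed within the main interval, as did 55 of 72 for knockdown-only shares. No paired analysis was possible because the groups share replicate numbers in the labels but each list is pooled over them; leaving out a replicate and the motif alternatives were not run. Depth is unknown, so a region missing from a list is one below its threshold, not one shown to be closed.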

Other observations

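Ranks over the regions that all 4 lists hold were compared only after the data were seen, and the genes named from them were chosen after their values were seen. Each list ranked the same 94562 regions by its own −log10 p, and the shift is a list's percentile rank minus the median of the other 3. Over these regions the rank correlation of the knockdown with the controls was 0.886 to 0.897, against 0.944 to 0.946 between controls; regions are not independent replicates. Hox genes stood lowest: their 40 regions had a mean shift of -6.52 percentile points in the knockdown (percentile 0.18 among random lists matched on regions and control rank), with 19 of 28 genes toward weaker ranks. Controls lay at percentiles 5.94 to 95.7, and the 7 alternatives run gave 0.06 to 1.18 for the knockdown. Ranked by fold, where the knockdown was at 1.18, the scrambled mCherry-negative list reached 99.15, about as far out on the other side. Hox genes lie side by side in a few clusters, while the random lists drew each gene separately across the genome. Regions of neighbouring genes can move together, so the Hox percentiles can be too extreme, and the 28 genes are not separate cases. Syncytiotrophoblast genes followed, with -3.42 over 85 regions (percentile 1.01, alternatives 0.64 to 4.09, controls 50.3 to 94.3) and Dlx3, a transcription factor gene of the placental labyrinth, at -12.9 (median of 8 regions, SD 10.6). Fibroblast genes stood highest, at 5.18 over 61 regions (percentile 99.8, alternatives 97.6 to 99.8). Of these 12 genes 8 stood toward stronger ranks, but 5 of 11 with peaks of at least 300 bp and 3 of 7 without chromosomes 1, 8, 10 and 11, so the mean rests on a few genes, led by Fbn1, the fibrillin gene, at 16.8 (13 regions, SD 22.1). Trophoblast stem cell genes were at -1.27 (percentile 16.1), a sign that turned when regions were ranked by fold (0.236). Giant cell genes were at 0.525 (percentile 72.9, but 1.00 in the scrambled mCherry-positive and 98.35 in the untransfected list, so control lists reach such percentiles too), which turned to -0.918 without those chromosomes and to -1.26 without the scrambled mCherry-positive list, while Hand1 stood at 12.5 over 12 regions, 10 of them toward stronger ranks.

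Single genes shifted more often in the knockdown than in any control rotation. Among 5644 genes with at least 5 such regions, 123 had a median shift above 10 percentile points and 108 one below -10 in the knockdown, against 18 to 24 and 21 to 30 in the controls. The knockdown's shifts were wider over all shared regions (SD 12.6 against 8.36 to 8.67), which by itself raises such counts in both directions, and whether lower depth or signal widened them is open. Toward stronger ranks stood E2f8 (19.3, 5 of 8 regions, SD 20.3), an atypical E2F gene of endoreduplicating giant cells, Csf2 (20.2, 5 of 5 regions), Rgcc (23.2, 6 of 6) and Yap1, the Hippo pathway coactivator gene (14.7, 11 of 14). Toward weaker ranks stood Dut, a dUTPase gene (-24.0, 5 regions), Slc7a11, a cystine transporter gene (-15.5, 7 regions), and Cdh2 (-10.9, 3 of 9 regions toward stronger). Spry4 (-9.35, 9 regions) and Krt8 (-7.00, 5 regions) also lay toward weaker ranks but within 10 points. The Cdx2 regions had a median of -2.74 over 5 regions and those of Tfap2c -4.27 over 16. Of placental gene families chosen after the data were seen, Psg genes had a mean of 6.35 over 23 regions (percentile 98.9, controls 26.7 to 39.3) and Prl genes -0.528 over 51 (percentile 55.8). Serpinb9 genes reached percentile 91.7 in the knockdown and 0.18 in the untransfected list. Ceacam genes were at 37.4 in the knockdown and 97.6 in the scrambled mCherry-negative list, and Rhox genes at 80.8 and 2.14. The placental cathepsins, the last family chosen, were at 31.6 in the knockdown. A control list alone can therefore also be extreme. Members of a gene family can lie side by side as well, so family percentiles can be too extreme in the same way. These families were not repeated under the alternatives.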
